A study of Mus musculus with 8 samples.

How the data were processed

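Polyadenylated RNA of mouse gonads at embryonic day 11.5 was sequenced with 100-base paired reads on a DNBSEQ-G400 instrument, per the labels' protocols. Embryos were sexed and genotyped for Kdm6b, and each library pooled 2 pairs of gonads. The growth protocol in the labels speaks of 4 samples, whereas 8 samples are listed, 2 for each of the 4 groups of sex and genotype, and all 8 were analysed. The labels name pre-granulosa cells for XX and pre-Sertoli cells for XY, but give the tissue as gonad and describe no sorting, so the values are taken as those of whole gonads. Groups and replicate numbers came from the sample titles, and every value column was matched to 1 sample by its title, with 0 columns left over.

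The submitters' processing notes name cutadapt 4.9, STAR 2.7.11, featureCounts 2.0.8 and DESeq2 2.11.40.8 with the mouse genome build GRCm38 (mm10). The strand and multimapping settings, the gene annotation release and the filters are not given in the sources used here. The deposited signal is a normalized count per gene: the authors divided featureCounts counts by 1 size factor per library, with the XX and XY libraries normalized separately in 2 tables of 48440 genes. The authors' deposited tables of their own DESeq2 comparisons give a log2 fold change with its standard error, a p-value and an adjusted p-value for Kdm6b-null over wild type within each sex. The deposited XX comparison carries no header, and its columns were identified from the XY table and from the means of the normalized counts. The deposited tables also hold a Wald score, which was not used. In every library 100% of the nonzero values were whole multiples of 1 step within a tolerance of 1e-06 of a step, and that step was read as 1 count. The depth obtained this way was 19121394 and 19234359 counts in the XX wild type libraries, 19783667 and 19828638 in XX Kdm6b-null, 19477084 and 19525527 in XY wild type, and 19578786 and 19107103 in XY Kdm6b-null libraries, and the 10 most abundant genes took 4.80 to 6.10% of the counts. A gene at 0 in a library could hold up to 3 counts, or 2.91 to 3.09 normalized counts.

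All tests done here used limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with the variance trend on mean expression and Benjamini-Hochberg adjustment at 0.05. A log2 fold change on this scale understates the change of genes with few counts. Genes were kept where the mean over the 4 libraries of a sex was at least 10, which left 16821 genes in XY and 17028 in XX. Genotype was the only term, and each sex was fitted alone because the authors normalized and tested the sexes apart. The difference between the XY and XX effects was tested on 17282 genes in 1 fit of the 8 libraries, as a difference of 2 within-table differences, so that a scale factor between the tables cancels. The residual degrees of freedom were 2 in each sex and 4 for the difference, and the prior degrees of freedom were 3.5, 3.35 and 3.69. The design assumed that a model of counts might be run on recovered reads. That was not done. The steps lay between 0.970 and 1.03 normalized counts, and a separate screen for recovered reads did not tell those closest to 1 from values rounded to whole numbers, so all tests of genes and lists used the normalized values. The step was used for the depths, the limit at 0, the comparison with sampling noise and the simulation, which rest on reading it as 1 count.

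For lists of genes camera was used with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. With an estimated correlation camera tests on the residual degrees of freedom, here 2 or 4, and so with little power whatever the correlation. The 22 lists of 309 genes (308 matched by symbol) were fixed before the data were examined, as were the designs, the rule for naming genes and all alternatives but the correction for GC content and length and the testis pathway without Sry. The lists cover Sry regulators, the testis and ovary pathways, FGF and ERK feedback, Leydig and steroidogenic genes, adrenal cortex, interstitial progenitors, coelomic epithelium, germ cells, mesonephros and duct, endothelium, erythroid cells, macrophages, and neural crest and neurons. They also cover proliferation, p53 targets, hypoxia and glycolysis, immediate early genes, H3K27 demethylases and Polycomb, Hox genes, the neighbours of Kdm6b, and a sex chromosome check. The rule named Kdm6b first, then Sry, Sox9, Fgf9, Amh, Wnt4, Fst, Kdm6a and Uty whatever their result. For each list it named up to 4 members past the threshold, or 1 or 2 with the smallest p where none passed. It also named the 10 genes with the largest change in each direction among the calls, with a group mean of at least 50 and groups that do not overlap, passing over predicted genes without a gene name. As limma made no calls, threshold members were taken from the adjustment over the list alone and the last part was applied to the calls in the authors' deposited tables, both after the counts were seen.

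On simulated data with the real means and depths, limma recovered 63 of 100 genes changed 2-fold and 90 of 95 changed 4-fold in XY, 65 of 99 and 75 of 95 in XX, and 30 of 100 and 72 of 100 for the difference. It called 5, 6 and 1 unchanged genes. The variances of the simulated genes were more alike than those of the real genes. The prior degrees of freedom were 71.1 in XY, 36.1 in XX and 37.6 for the difference, against 3.5, 3.35 and 3.69 in real data. The counts of recovered genes therefore need not hold for the real data. Camera picked out a simulated list of 20 genes shifted 1.4-fold in all 3 comparisons and picked out no unshifted list. It was run with the preset correlation, and the simulated genes varied independently of each other. The simulation therefore cannot show whether camera calls unshifted lists whose members move together. In the real XY data the estimated correlation was 0.801 for endothelial and 0.689 for erythroid genes.

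Alternatives covered pseudocounts of 0.5 and 5, no filter and a mean of at least 50, trimmed-mean scaling and median centring, limma without the trend and with robust estimation, the replicate number as a block, all libraries in 1 fit, and each library left out in turn. For the trend correction added after the data were seen, GC content and length of the longest transcript came from the GENCODE M21 annotation of GRCm38, which holds 48058 of the 48440 gene identifiers (99.2%) and 99.7% of the tested genes of each sex. Each library's trend with both was removed with a spline of 4 degrees of freedom. Gene coordinates are those of the authors' deposited tables. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.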

Results

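Gene expression was measured by sequencing polyadenylated RNA from mouse gonads at embryonic day 11.5, when the bipotential gonad of XY embryos switches on the Y-linked gene Sry. Wild type gonads were compared with gonads lacking Kdm6b, which encodes a histone demethylase that removes repressive methyl groups from histone H3. The 4 groups were XX wild type, XX Kdm6b-null, XY wild type and XY Kdm6b-null, with 2 libraries in each, and every library pooled 2 pairs of gonads. Each library held between 19107103 and 19828638 counts on genes, and 3 counts, taken as the limit that a value of 0 allows, were worth 2.91 to 3.09 normalized counts per library. This limit and the standard deviations below leave out any error that the library amplification added to all counts alike. The replicate libraries of every group, which are separate pools, differed by more than sampling noise. The median chi-square per gene was 4.27 in XX wild type, 1.25 in XX Kdm6b-null, 1.44 in XY wild type and 2.42 in XY Kdm6b-null, and the means, raised by fewer genes, were 10.4 to 33.8. The labels do not say whether the pools of a group came from separate litters. The p-values of single genes therefore measure the spread between these pools. Camera with the preset correlation compares the genes of a list with all other genes. Its p-values do not measure that spread, so a small one does not show that a change repeats across pools.

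Kdm6b transcript was lower in all 4 null libraries than in any wild type library of the same sex. In XY gonads Kdm6b averaged 3290 ± 154 normalized counts (SD, n = 2) in wild type and 1137 ± 142 (SD, n = 2) in the null, which is 34.6% of wild type. In XX gonads it averaged 2507 ± 409 (SD, n = 2) in wild type and 1187 ± 87.1 (SD, n = 2) in the null, or 47.4% of wild type. The log2 fold changes were -1.54 (SE 0.11) in XY and -1.07 (SE 0.14) in XX by limma, with limma adjusted p = 0.12 and 0.19. The authors' deposited table gave DESeq2 log2 fold changes of -1.53 (adjusted p = 8.2e-25) in XY and -1.08 (adjusted p = 7.1e-07) in XX. Kdm6b (ENSMUSG00000018476.7) lies on chromosome 11 at 69398508 to 69413675 (GRCm38), and the part of the gene that the null allele lacks is not given in the sources used here. Kdm6bos, an antisense transcript inside it at 69401513 to 69402700, had 27.7 and 25.92 normalized counts in the XY wild type libraries, 24.25 and 19.22 in the XX wild type libraries, and 0 in all 4 null libraries. Because the strand setting of the counting is not given, reads of Kdm6b and Kdm6bos may not be fully separated. The sex labels matched the sex-linked genes: Xist, the RNA that silences an X chromosome, ranged from 33220 to 49580 normalized counts in XX libraries and from 15.83 to 33.89 in XY libraries (normalized separately), and Sry was at 0 in all 4 XX libraries.

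The XY comparison asks what loss of Kdm6b does to the gonad as testis determination begins. Genes of the testis pathway were lower in XY Kdm6b-null gonads: 19 of the 21 measured members had negative log2 fold changes, with a median of -0.43. Sry, the testis-determining switch, averaged 65.57 ± 11.6 normalized counts (SD, n = 2) in XY wild type and 12.84 ± 9.43 (SD, n = 2) in XY Kdm6b-null gonads. Inhbb, an activin and inhibin subunit made by Sertoli cells, averaged 583 ± 39.7 and 220.3 ± 75.7 (SD, n = 2 each). Dmrt1, a transcription factor that maintains male fate, averaged 131.1 ± 7.74 and 56.67 ± 4.28 (SD, n = 2 each). Hox genes, which pattern the body axis, were higher in the null, with positive log2 fold changes in 34 of 37 measured members and a median of 0.41. The Hox median was 0.24 without XY wild type replicate 2. Neither the testis pathway nor the Hox list passed by camera with an estimated correlation (adjusted p = 0.24 for each).

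By camera the testis pathway list was lower (adjusted p = 4.3e-09, and adjusted p = 0.24 with an estimated correlation), and adjusted over the list alone 6 of its 21 members fell by limma, against 0 over all genes tested. The 6 were Inhbb (log2 fold change -1.44, SE 0.24), Dmrt1 (-1.20, SE 0.20), Sry (-2.45, SE 0.55), Cyp26b1, a retinoic acid-degrading enzyme (-0.62), Cbln4, a secreted Sertoli cell marker (-1.57), and the inhibin subunit Inha (-0.59). The median in each null library was close to that of the list, at -0.42 in replicate 1 and -0.45 in replicate 2. In the same null libraries the macrophage medians were 0.20 and 0.48 and the endothelial medians were -0.12 and -0.26 relative to the wild type mean. Sox9, Fgf9 and Amh, which act further along the pathway, did not pass. Sox9, the Sertoli cell transcription factor activated by SRY, had 910.1 and 766.6 normalized counts in wild type and 1021 and 495.1 in the null (log2 fold change -0.23). Fgf9, a growth factor that sustains Sox9, had a log2 fold change of -0.01, and Amh, the hormone that removes the Müllerian duct, was near 10 in every library (0.04).

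The list of Sry regulators, genes of the early gonad linked to the activation of Sry, was split in XY gonads, with 9 members higher and 9 lower and a median of 0.01 (camera adjusted p = 0.61). Adjusted over the list alone, Lhx9, a LIM homeobox factor of the early gonad, fell by limma from 1963 ± 374 to 1008 ± 111 normalized counts (SD, n = 2 each). Nr5a1, the steroidogenic master regulator, had a log2 fold change of -0.86, and Gata4, which is needed for the gonad to form, had -0.68, and neither passed. The ovary pathway list was also lower by camera, with a median of -0.34 and 10 of 14 members negative (adjusted p = 0.028, and adjusted p = 0.55 with an estimated correlation). None of its members passed adjusted over the list alone, and the smallest p-values belonged to Nr0b1, an X-linked antagonist of Sry action (-0.84), and the transcription factor Runx1 (-0.58). That list's camera call was lost without XY wild type replicate 1 (median -0.16, adjusted p = 0.13) without XY Kdm6b-null replicate 1 (-0.17, adjusted p = 0.66) and with no filter on low values (-0.34, adjusted p = 0.12). Wnt4, a signal of ovarian fate, had 2217 and 2523 normalized counts in XY wild type and 1425 and 3089 in the null (log2 fold change -0.17). Fst, which encodes the activin antagonist follistatin, had a log2 fold change of -0.39.

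The Hox list was higher in XY Kdm6b-null gonads by camera (adjusted p = 8.8e-13, and adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, 3 of the 37 members rose by limma: Hoxa6 (log2 fold change 0.68), Hoxa3 (0.55) and Hoxb5 (0.59). Without XY wild type replicate 2 the median was 0.24 (camera adjusted p = 3.8e-06). Mesonephros and duct genes, from the tissue beside the gonad, were at -0.27 and 0.28 in those null libraries, with a list median of 0.01 (camera adjusted p = 0.82). In the list of H3K27 demethylases and Polycomb genes, which includes genes that remove or place the mark Kdm6b acts on, the median was -0.03 (camera adjusted p = 0.69). Its X-linked demethylase Kdm6a had a log2 fold change of -0.07 and the Y-linked Uty had 0.01. The members with the smallest p were Ring1, a Polycomb subunit (log2 fold change 0.36), and then Eed (log2 fold change -0.19).

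**Figure D1:**
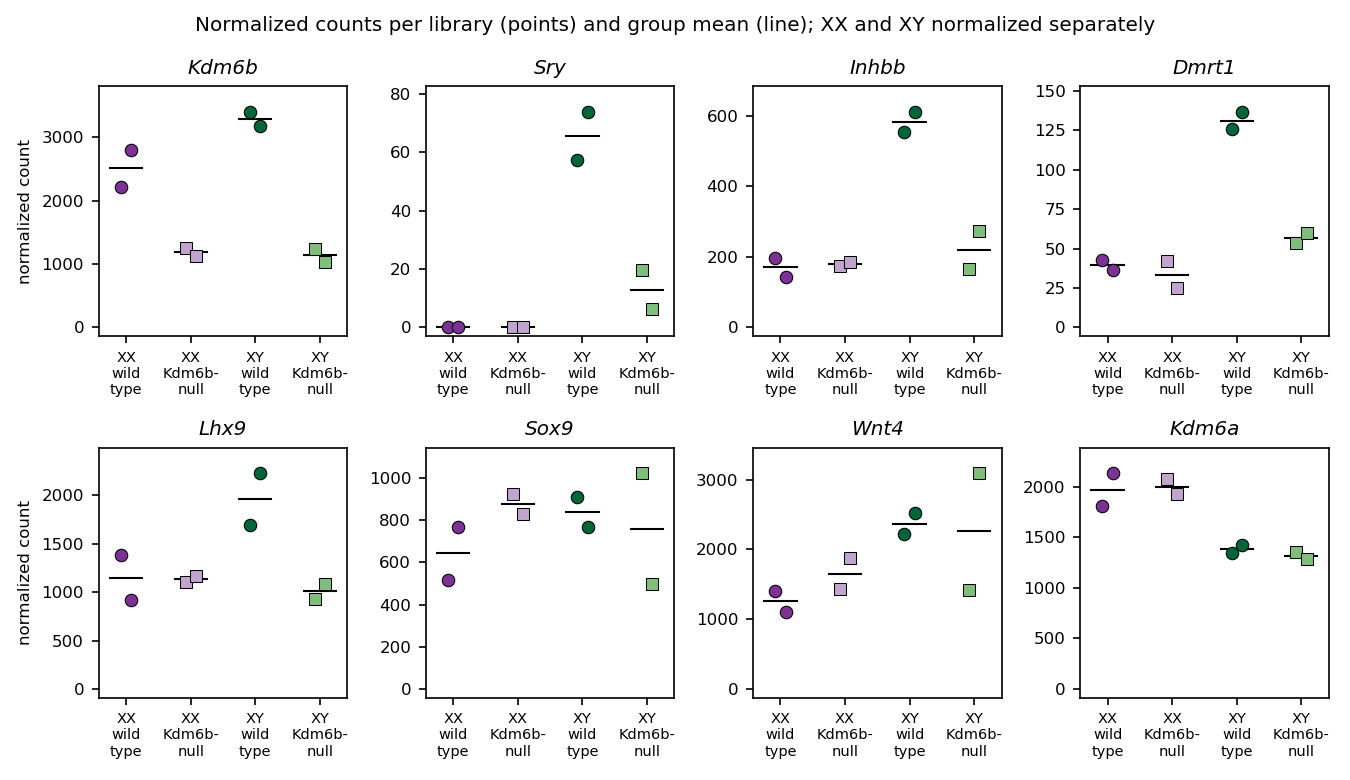
Normalized counts (vertical axis) of 8 genes in each of the 4 groups, with 1 point per library and a line at the group mean; XX and XY libraries were normalized separately. Kdm6b is lower in the null libraries of both sexes, and Sry, Inhbb, Dmrt1 and Lhx9 are lower in the XY null libraries than in the XY wild type libraries.

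Markers of other cell types also differed between the XY libraries. Macrophage genes were higher in the null, with a median log2 fold change of 0.35 and 10 of 11 positive (camera adjusted p = 1.1e-05, and adjusted p = 0.55 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor, rose by limma adjusted over the list alone, from 489.1 ± 14.6 to 812.7 ± 5.23 normalized counts (SD, n = 2 each). The macrophage median was 0.20 without XY Kdm6b-null replicate 2, with camera adjusted p = 0.0082. Erythroid genes had a median of 0.45 (camera adjusted p = 0.014, and adjusted p = 0.82 with an estimated correlation). That value rested on XY Kdm6b-null replicate 2, whose own median was 1.26 against -0.28 in replicate 1. Without replicate 2 of the null the erythroid median was -0.28 (camera adjusted p = 0.51), without replicate 1 of the null it was 1.26, and without XY wild type replicates 1 and 2 in turn it was 0.16 and 0.91. Hbb-bt, an adult beta globin that can share reads with its near-identical copy Hbb-bs, rose by limma adjusted over the list alone (2.45). Germ cell genes had a median of 0.29, with 14 of 15 positive (camera adjusted p = 0.018, and adjusted p = 0.82 with an estimated correlation). The germ cell median was -0.04 without XY wild type replicate 1 (camera adjusted p = 0.96), 0.14 without XY Kdm6b-null replicate 1 (adjusted p = 0.57), 0.64 without XY wild type replicate 2 and 0.72 without XY Kdm6b-null replicate 2. With all 8 libraries in 1 fit it was 0.29 (camera adjusted p = 0.067). Its members with the smallest p were the stem cell factor receptor Kit (0.44) and the pluripotency factor Nanog (0.81).

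Endothelial genes were lower in XY Kdm6b-null gonads, with 9 of 10 negative and a median of -0.21 (camera adjusted p = 0.0042, and adjusted p = 0.82 with an estimated correlation). The endothelial median was 0.03 without XY wild type replicate 2 (camera adjusted p = 0.97), -0.12 without XY Kdm6b-null replicate 2 (adjusted p = 0.11) and -0.35 without XY wild type replicate 1. No endothelial member passed adjusted over the list alone, the smallest p-values being those of the receptor gene Tek (-0.48) and of Cldn5, a tight junction gene (-0.24). All 14 hypoxia and glycolysis genes had negative log2 fold changes, with a median of -0.18 (camera adjusted p = 8.4e-04, and adjusted p = 0.55 with an estimated correlation). The glycolytic enzyme gene Ldha (-0.32) and the angiogenic factor Vegfa (-0.23) had its smallest p-values, and without XY Kdm6b-null replicate 1 the median was -0.11 (camera adjusted p = 0.22). The remaining lists did not pass by camera in XY (adjusted p = 0.058 to 0.90). Their medians, each with the member of smallest p, were -0.01 for FGF and ERK feedback (Spry4 -0.49), -0.17 for Leydig and steroidogenic genes (Cyp11a1, which starts steroid synthesis, -1.14), 0.10 for adrenal cortex (Akr1b7 0.24), -0.05 for interstitial progenitors (Nr2f2 0.42) and 0.14 for coelomic epithelium (Upk1b 0.65). In the mesonephros and duct list Pax2 (0.39) had the smallest p. They were -0.09 for neural crest and neurons (Hand2 0.41 and Th -0.88), -0.04 for proliferation (Ccnb1 -0.10), 0.01 for p53 targets (Ccng1 -0.16), -0.05 for immediate early genes (Fos 1.02), -0.07 for the neighbours of Kdm6b and 0.01 for the sex chromosome check (Ddx3y 0.05). Among the neighbours, Atp1b2, a sodium pump subunit, fell by limma adjusted over the list alone (-0.78), and Shbg had a log2 fold change of -2.03 without passing.

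**Figure D2:**
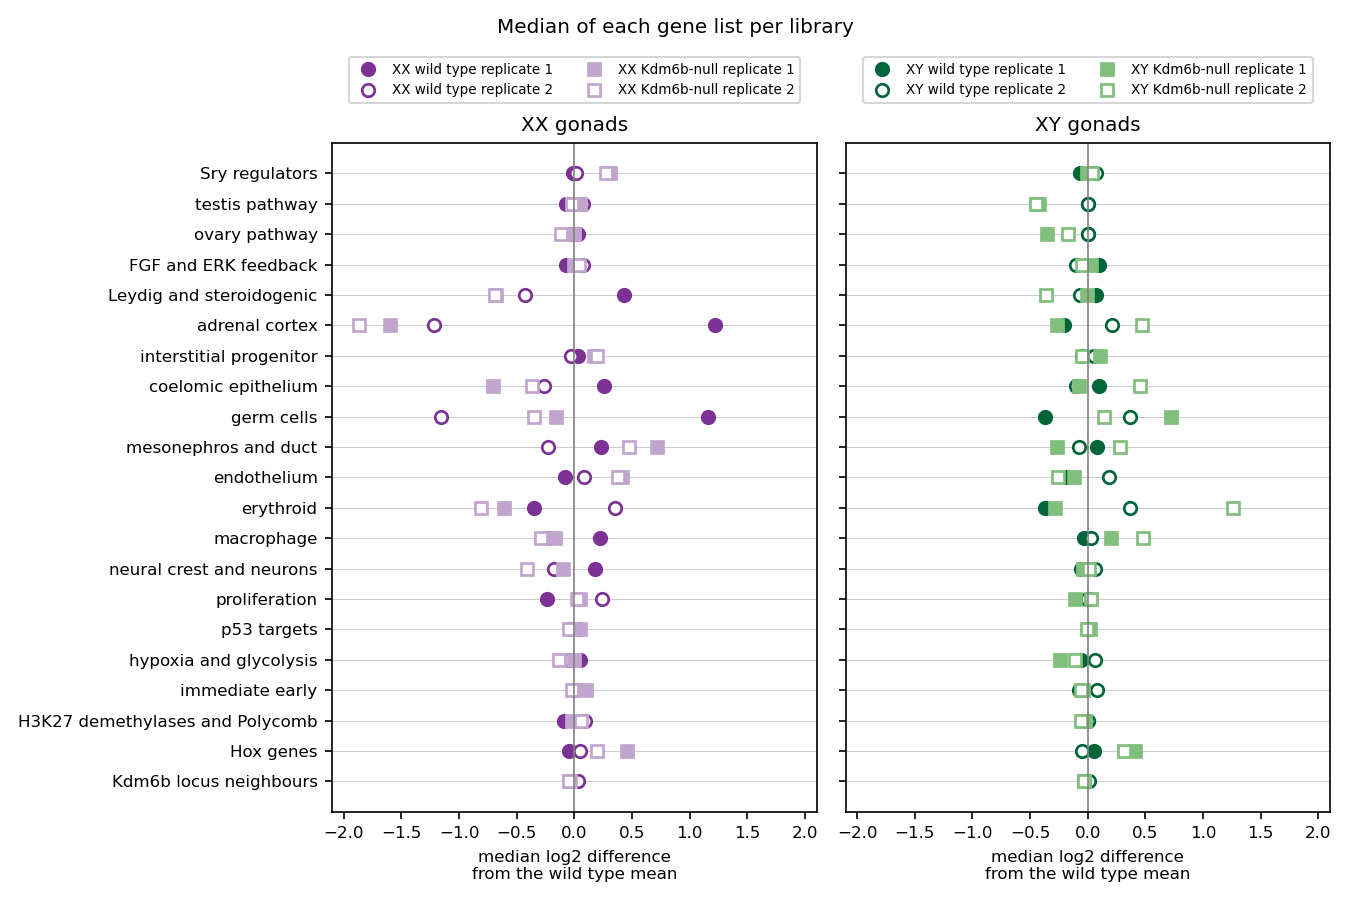
Median log2 difference of each gene list from the wild type mean of the same sex, 1 point per library, with XX and XY libraries in separate panels. The testis pathway medians of the XY null libraries are -0.42 and -0.45, and the erythroid medians of those libraries are -0.28 and 1.26.

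Over all genes, limma called 0 of 16821 genes in XY, while 834 had an unadjusted p under 0.05 (355 higher and 479 lower) where 841 are expected by chance. The smallest limma adjusted p was 0.12. The authors' deposited table held 72 genes with a DESeq2 adjusted p under 0.05, 22 higher and 50 lower in the null. All 72 had the same direction and an unadjusted p under 0.05 by limma, which used the same libraries and is no independent check. The highest of them with a group mean of at least 50 were Ctse, the protease cathepsin E (log2 fold change 4.53 in the authors' deposited table), mt-Nd3, a mitochondrial respiratory chain gene (4.10), and Ros1, a receptor tyrosine kinase (2.64). They were followed in the authors' deposited table by Hbb-bt (2.39), the axonemal dynein Dnah8 (1.69), Nr1h5 (1.22), the detoxifying enzyme Glo1 (1.19), G6pc2 (1.16), the neuronal gene Dcx (1.10) and Eda (0.96). The lowest in the authors' deposited table were Scrt2, a neuronal repressor (-2.92), the guanylate-binding protein Gbp2b (-2.78), Nrn1 (-2.53), the water channel Aqp5 (-2.50) and the calcium pump Atp2b3 (-2.38). Kdm6b (-1.53), Pnliprp2 (-1.53), Kctd14 (-1.46), Inhbb (-1.41) and Pitpnm3 (-1.39) completed that set of the authors' deposited table. These genes were picked from the authors' calls after the limma counts were seen. Sry had a log2 fold change of -2.35 and a DESeq2 adjusted p of 0.084 in the authors' deposited table, and Lhx9 had -0.96 and 3.4e-05. Left out in turn, each library but XY wild type replicate 1 gave 2 limma calls, under the assumption that the lone library of the group varied like the others. They were Trim12a and Rps2-ps13 without XY wild type replicate 2, Gm13394 and Gm15772 without XY Kdm6b-null replicate 1, and Gm15772 and Hmgb1-ps7 without XY Kdm6b-null replicate 2, named after their values were seen.

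The XX comparison asks what the same loss does in gonads without Sry. Endothelial genes were higher in XX Kdm6b-null gonads, with all 10 members positive and a median log2 fold change of 0.39. Cdh5, the cadherin of endothelial junctions, averaged 2242 ± 346 normalized counts (SD, n = 2) in XX wild type and 3884 ± 29.1 (SD, n = 2) in the null. Erythroid genes were lower, with 11 of 12 negative and a median of -0.70, and the embryonic beta globin Hbb-y averaged 116200 ± 2950 and 53950 ± 923 (SD, n = 2 each). Genes that regulate Sry were higher in 17 of 18 cases (median 0.28), and Hox genes in 26 of 36 (median 0.21). None of these lists passed by camera with an estimated correlation (adjusted p = 0.66 to 0.78). The erythroid median was -1.13 without XX wild type replicate 1 and -0.32 without replicate 2, and the Hox median was 0.09 and 0.45. The testis pathway list had a median of 0.03 in XX, with 11 members positive and 9 negative (camera adjusted p = 0.77).

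The 2 XX wild type libraries stood further apart than any other pair, with a correlation of 0.962 between their log2 values against 0.9796 to 0.9851 in the other groups. The adrenal cortex median was 1.22 above the wild type mean in replicate 1 and -1.22 in replicate 2, and the germ cell median was 1.16 and -1.16. Mitochondrial genes took 3.12% of the counts in XX wild type replicate 1, 2.55% in replicate 2, and 1.90 to 2.22% in the other 6 libraries.

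The endothelial list passed by camera (adjusted p = 2.8e-06, and adjusted p = 0.66 with an estimated correlation), and 7 of 10 members rose by limma adjusted over the list alone. They included Plvap, a component of the diaphragms of vessel walls (log2 fold change 0.93), Cdh5 (0.80), and the receptor genes Tie1 (0.71) and Tek (0.49). The erythroid list passed as lower (camera adjusted p = 8.7e-05, and adjusted p = 0.66 with an estimated correlation), with 5 members that fell by limma adjusted over the list alone. Among them were the globins Hbb-y (-1.11), Hba-a1 (-1.25) and Hbb-bt (-1.97), the last of which have near-identical copies, and the haem synthesis enzyme Alas2 (-0.82). The erythroid median was -0.32 without XX wild type replicate 2 (camera adjusted p = 0.11) and -1.13 without XX wild type replicate 1. The Sry regulators passed as higher (camera adjusted p = 2.7e-04, and adjusted p = 0.66 with an estimated correlation). Of these, the transcriptional coactivator Cited2 rose from 844.4 ± 7.41 to 1270 ± 8.28 normalized counts (SD, n = 2 each) and the kinase Map3k4 from 1536 ± 156 to 2283 ± 63.3 (SD, n = 2 each), by limma adjusted over the list alone.

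The Hox list passed as higher in XX (camera adjusted p = 7.1e-04, and adjusted p = 0.78 with an estimated correlation), with 6 members that rose by limma adjusted over the list alone, among them Hoxc9 (log2 fold change 1.16), Hoxa7 (0.64), Hoxd3 (0.79) and Hoxc6 (1.02). That median was 0.09 without XX wild type replicate 1 (camera adjusted p = 0.075), 0.20 without XX Kdm6b-null replicate 1 (adjusted p = 0.14), 0.45 without XX wild type replicate 2 and 0.46 without XX Kdm6b-null replicate 2. Mesonephros and duct genes had a median of 0.38 in the same libraries (camera adjusted p = 0.11), with the duct factor Gata3 at 0.83 and Wnt9b at 0.52. Leydig and steroidogenic genes passed as lower (median -0.62, camera adjusted p = 0.025, and adjusted p = 0.66 with an estimated correlation), with no member past the threshold adjusted over the list alone. The electron carrier Fdx1 (-0.49) and the steroid hydroxylase Cyp17a1 (-1.84) had its smallest p-values. In the same libraries the adrenal cortex median was -1.43 (camera adjusted p = 0.16), with Mc2r at 0.86 and Cyp11b1 at -4.57 by limma, and the Leydig median was -0.16 without XX wild type replicate 1 (camera adjusted p = 0.047), -0.95 without XX wild type replicate 2 and -0.64 without XX Kdm6b-null replicate 2 (adjusted p = 0.063). With genes kept only at a mean of at least 50 the Leydig median was -0.46 (camera adjusted p = 0.068).

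The other lists did not pass by camera in XX, although some members passed adjusted over the list alone. Germ cell genes had a median of -0.28 (camera adjusted p = 0.95), while Kit rose from 1184 ± 162 to 2213 ± 189 normalized counts (SD, n = 2 each) and the pluripotency-linked RNA-binding protein gene Lin28a rose too (0.65) by limma adjusted over the list alone. Coelomic epithelium genes had a median of -0.54 (camera adjusted p = 0.11), with Upk1b (-1.23) and the keratin Krt7 (-0.99) lower and Lrrn4 (0.46) higher by limma adjusted over the list alone. Interstitial progenitor genes had a median of 0.18 (camera adjusted p = 0.062), and the nuclear receptor Nr2f1 (0.75) and the chemokine Cxcl12 (0.63) rose by limma adjusted over the list alone. In the ovary pathway (median -0.19, camera adjusted p = 0.58) the Wnt receptor Fzd1 rose by limma adjusted over the list alone (0.54), while Wnt4 had 1411 and 1110 normalized counts in wild type and 1430 and 1875 in the null, and Fst had a log2 fold change of -0.52. In the testis pathway Fgf9 had the smallest p, with 137.8 and 202.3 normalized counts in XX wild type and 68.76 and 85.87 in the null (log2 fold change -1.11), Sox9 had a log2 fold change of 0.47 and Amh 0.19. Medians were -0.01 for FGF and ERK feedback (Spry4 -0.64), -0.27 for macrophages (Mrc1 -0.43), -0.30 for neural crest and neurons, 0.01 for proliferation (Plk1 0.63) and 0.01 for p53 targets (Sesn2 0.68). They were -0.06 for hypoxia and glycolysis (Ndrg1 -0.93), 0.06 for immediate early genes (Egr1 -0.96), 0.02 for H3K27 demethylases and Polycomb (Bmi1 -0.38, Kdm6a 0.03) and -0.05 for the Kdm6b neighbours, of which Fxr2 rose by limma adjusted over the list alone (0.47). Only Xist of the sex chromosome check was measured in XX (-0.37), and Uty had 0.9702 normalized counts in XX wild type replicate 1 and 0 in the other 3 XX libraries.

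Over all genes, limma called 0 of 17028 genes in XX, with 2383 at an unadjusted p under 0.05 (1591 higher and 792 lower) where 851 are expected by chance, and the smallest limma adjusted p was 0.10. The authors' deposited table held 407 genes with a DESeq2 adjusted p under 0.05, 286 higher and 121 lower. All 407 had the same direction by limma, 401 of them with an unadjusted p under 0.05, again from the same libraries and so no independent check. The limma count depended on the XX wild type pair: 621 genes passed without replicate 1 (405 higher and 216 lower) and 3550 without replicate 2 (2373 higher and 1177 lower), each time with the lone wild type library assumed to vary like the null libraries. These sets shared 423 genes, 398 of them with the same direction, and 316 of the authors' 407 calls were in both.

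Among the calls in the authors' deposited table that were higher in XX Kdm6b-null gonads, the largest log2 fold changes were those of cardiac actin Actc1 (2.50), the neuronal adhesion molecule Dscam (2.41), the neuropeptide receptor Npbwr1 (2.38) and the myeloid peroxidase Mpo (2.03). The others named by the rule from the authors' deposited table were skeletal actin Acta1 (1.94), the neural factor Pou3f2 (1.78), the inflammation inhibitor Tnfaip3 (1.69), Nup62cl (1.68), Ros1 (1.54) and the collagen Col5a3 (1.53). The largest decreases in the authors' deposited table belonged to Cyp11b1 (-7.14) and Cyp21a1 (-6.59), steroid enzymes of the adrenal cortex, and to genes best known from liver and yolk sac: Apoa1 (-6.91), Afp (-6.81), Ttr (-6.06), Kng1 (-6.01), Apob (-5.78), Ugt2b34 (-4.78) and Gc (-4.62), with the neuropeptide gene Cartpt (-4.55). Afp, alpha-fetoprotein, had 11140 normalized counts in XX wild type replicate 1, 149.7 in replicate 2, and 43.85 and 56.57 in the null. Cyp11b1 had 417.2 normalized counts in XX wild type replicate 1, 7.081 in replicate 2, and 1.993 and 1.01 in the null, the null values being below the limit set by 3 counts, so that the size of its fold change depends on the fit. Of the 121 lower calls in the authors' deposited table, 29 were over 2-fold higher in XX wild type replicate 1 than in replicate 2 and 5 the other way, whereas of the 286 higher calls the numbers were 0 and 5.

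The difference between the sexes in the effect of Kdm6b loss was tested over all 8 libraries. The testis pathway differed, with 15 of 21 members lower in the XY effect than in the XX effect and a median difference of -0.43 (camera adjusted p = 0.0036, and adjusted p = 0.24 with an estimated correlation). Sry, at 0 in all XX libraries, can only show its XY effect, and without it 14 of 20 members were lower, with a median of -0.34 (camera adjusted p = 0.0090, and adjusted p = 0.32 with an estimated correlation). With genes kept only at a mean of at least 50 the call was lost (median -0.34, camera adjusted p = 0.059). Adjusted over the list alone, Inhbb (-1.53), Cyp26b1 (-0.85) and Cbln4 (-1.83) differed by limma. The Sry regulators differed with 16 of 18 members lower in the XY effect and a median of -0.41 (camera adjusted p = 5.7e-05, and adjusted p = 0.24 with an estimated correlation), with the smallest p-values in Map3k4 (-0.52) and Cited2 (-0.50). Without XX wild type replicate 1 that median was -0.25, and the testis pathway median was -0.22 without XY wild type replicate 2 (camera adjusted p = 6.6e-04). Hox genes had a median difference of 0.06 (camera adjusted p = 0.96). None of the genes named in advance passed over all genes: the differences were -0.47 for Kdm6b, -0.71 for Sox9, 1.10 for Fgf9, -0.15 for Amh, -0.56 for Wnt4, 0.13 for Fst and -0.10 for Kdm6a.

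Markers of vessels and blood differed as well. Endothelial genes were lower in the XY effect in 10 of 10 cases, with a median of -0.57 (camera adjusted p = 7.2e-08, and adjusted p = 0.46 with an estimated correlation) and 7 members past the threshold adjusted over the list alone, led by Plvap (-1.06). Erythroid genes were higher in the XY effect in 12 of 12 cases, with a median of 1.17 (camera adjusted p = 2.4e-05, and adjusted p = 0.52 with an estimated correlation) and 3 members past the threshold adjusted over the list alone, among them Hbb-bt (4.42) and Hba-a1 (2.26). The erythroid difference was 0.37 without XY Kdm6b-null replicate 2, 0.65 without XX wild type replicate 2 and 1.91 without XY Kdm6b-null replicate 1. Macrophage genes were higher in the XY effect in 11 of 11 cases (median 0.46, camera adjusted p = 2.7e-05, and adjusted p = 0.46 with an estimated correlation), with Csf1r at 0.77, and their median was 0.28 without XX wild type replicate 1 and 0.88 without XX wild type replicate 2. Coelomic epithelium genes had a median difference of 0.49 (camera adjusted p = 0.0090, and adjusted p = 0.52 with an estimated correlation). It was 0.16 without XX wild type replicate 1 (camera adjusted p = 0.13), 0.43 without XY Kdm6b-null replicate 2 (adjusted p = 0.39), 0.32 without XX Kdm6b-null replicate 1 and 0.81 without XX wild type replicate 2. The other 16 lists did not pass. No camera call of the XY, XX or difference tests held with an estimated correlation. The test with an estimate uses the few residual degrees of freedom, so a lost call need not mean correlated genes. For the testis pathway in XY the estimate was -0.007, below the preset 0.01, yet the unadjusted camera p went from 3.9e-10 to 0.021. For endothelial genes in XY the estimate was 0.801. Over single genes limma called 0 of 17282 differences, with 1443 at an unadjusted p under 0.05 where 864 are expected by chance, and no other tool was run for this contrast. Without XX wild type replicate 2 the limma count was 44.

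The log2 fold changes of both sexes were weakly related across 16567 genes, with Pearson's r = 0.17 and Spearman's rho = 0.17. Genes are not independent replicates, so no p is given. Pearson's r was 0.06 without XX wild type replicate 1. It was 0.09 without XX Kdm6b-null replicate 1, XY wild type replicate 1 or XY Kdm6b-null replicate 2 in turn. In the same order Spearman's rho was 0.16, 0.11, 0.07 and 0.11. The authors' deposited tables called 14 genes in both sexes among 14686 genes with an adjusted p in both. Of these 14, 3 were higher in both, where independent lists would share 0.37, and 8 were lower in both, where 0.35 are expected. The 8 include Kdm6b itself, whose decrease in both sexes follows from the null allele. The genes higher in both of the authors' deposited tables were G6pc2, Scrn1 and Ros1. Those lower in both of the authors' deposited tables were Kdm6b, the calcium channel Cacna1g, Ifitm1, Serpinb6a, the cell cycle regulator Ccnd1 (-0.49 in each sex), Gm15920, Gm2044 and the ribosomal RNA locus Rn18s-rs5.

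The other 3 genes went in opposite directions, where 1 is expected, and all lie on chromosome 17 between 30592866 and 33956001 (GRCm38). Glo1, which detoxifies methylglyoxal, had 1487 and 1995 normalized counts in XY wild type and 4147 and 3797 in XY Kdm6b-null gonads, but 3200 and 4692 in XX wild type and 1352 and 1432 in XX Kdm6b-null gonads (normalized separately). In the authors' deposited tables its log2 fold changes were 1.19 in XY and -1.50 in XX. Dnah8, its neighbour, had 1.69 in XY and -1.97 in XX, and the ribosomal protein gene Rps18 had 0.92 and -0.90, in the authors' deposited tables. Rps18 has processed copies elsewhere in the genome whose reads can be assigned to it. The differences between the sexes by limma were 2.68 for Glo1, 3.67 for Dnah8 and 1.86 for Rps18, and none passed over all genes.

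**Figure D3:**
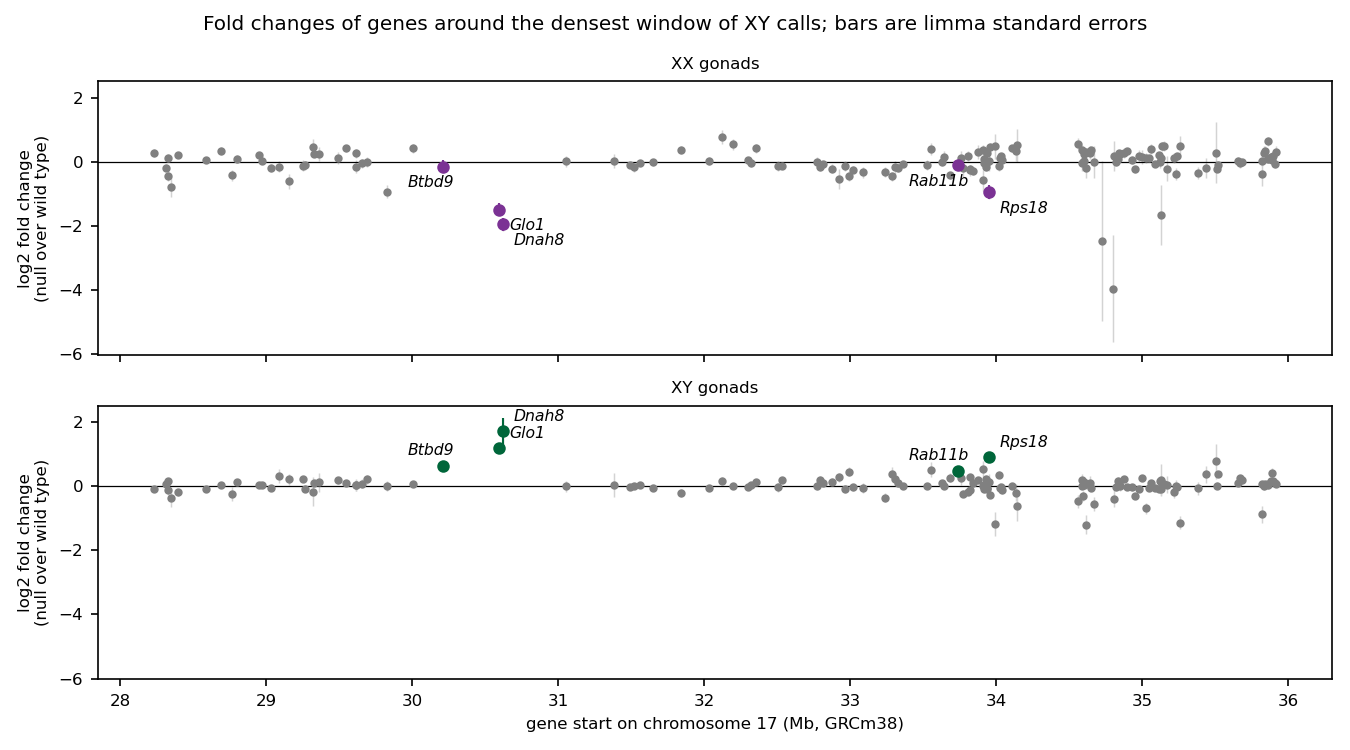
Log2 fold change, null over wild type, of genes along chromosome 17 in XX (upper panel) and XY gonads (lower panel), with limma standard errors as bars; the horizontal axis is the gene start in Mb (GRCm38). Glo1, Dnah8 and Rps18 are below 0 in XX and above 0 in XY, while Btbd9 and Rab11b, coloured because the authors called them in XY, are at -0.14 and -0.10 in XX.

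Levels in wild type gonads of each sex give the background of the pathway genes, and since the tables were normalized separately they were not tested against each other. Sry was at 0 in both XX wild type libraries. Inhbb averaged 583 ± 39.7 normalized counts in XY and 170.8 ± 38.4 in XX wild type gonads (SD, n = 2 each, normalized separately). Dmrt1 averaged 131.1 ± 7.74 in XY and 39.55 ± 4.44 in XX, and Cbln4 averaged 99.35 ± 16.0 and 21.86 ± 4.85 (SD, n = 2 each, normalized separately). In XY Kdm6b-null gonads these means were 220.3 ± 75.7 for Inhbb, 56.67 ± 4.28 for Dmrt1 and 33.35 ± 10.8 for Cbln4 (SD, n = 2 each). Sox9 had 910.1 and 766.6 normalized counts in XY and 515.2 and 768.8 in XX wild type gonads, and Wnt4 averaged 2370 ± 217 and 1260 ± 213 (SD, n = 2 each, normalized separately).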

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

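The tests of cell shares behind the testis pathway, of the testis pathway without Sry and of mesonephric tissue behind the Hox genes were chosen after the results were seen.

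The testis pathway was picked out because its XY and XX effects differed, by a median log2 of -0.43 (camera adjusted p = 0.0036, and adjusted p = 0.24 with an estimated correlation), or -0.22 without XY wild type replicate 2, -0.34 without Sry (which is at 0 in XX), and -0.34 with a mean of at least 50, where the call was lost (camera adjusted p = 0.059). The tables argue against a trend with GC content or gene length behind the XY decrease, since after its removal the median over the list was -0.44 (camera adjusted p = 2.9e-09 with the preset correlation), against -0.43 before (adjusted p = 0.24 with an estimated correlation). A lower share of gonadal cells in the XY null pools cannot be told apart from lower expression per cell. The test took a lower share to raise the markers of all other cell types alike. That need not hold, since its 6 lists include germ cells, which lie within the gonad. The mean changes of those lists ranged from -0.19 (endothelium) to 0.49 (erythroid), but libraries of the same group spread as far (a variance ratio F of 0.47 for list by genotype against list by library). The ovary pathway list was also lower in XY, with a median of -0.34 (camera adjusted p = 0.028, and adjusted p = 0.55 with an estimated correlation). That median was -0.16 without XY wild type replicate 1. The Sry regulators were split, with 9 higher and 9 lower (median 0.01). Adjusted over the list alone, 1 member (Lhx9) fell by limma and 0 rose. With the p-values of the authors' deposited table adjusted in the same way, 3 members fell and 0 rose. An effect of Kdm6b loss on the testis genes of XY gonads and a delay of gonad growth within embryonic day 11.5 were not tested and stay open.

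Glo1, Dnah8 and Rps18 were picked out because their changes went in opposite directions in XY and XX gonads, with differences of 2.68, 3.67 and 1.86 on the log2 scale. A strain or haplotype variant at the locus that differed among the pooled embryos cannot be told apart from an effect of Kdm6b on these genes. The densest 4 Mb of the authors' XY calls held 5 of 71 calls, where 95% of 10000 random placements held at most 4 and 96 were as dense (p = 0.01), but Glo1, Dnah8 and Rps18 were 3 of the 5 and had raised the question. The other 2, Btbd9 and Rab11b, are too few to decide. The labels give no strain, and an effect of Kdm6b that has opposite signs in the sexes was not tested and stays open.

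Hox genes were higher in the null gonads of both sexes, by a median log2 of 0.41 in XY (0.24 without XY wild type replicate 2) and 0.21 in XX (0.45 without XX wild type replicate 2 and 0.46 without XX Kdm6b-null replicate 2), but the camera adjusted p with an estimated correlation was 0.24 in XY and 0.78 in XX. A trend with GC content or gene length is argued against as the whole cause, with medians after its removal of 0.39 in XY (camera adjusted p = 3.3e-12) and 0.27 in XX (camera adjusted p = 0.0013), both with the preset correlation. More mesonephric tissue in the null pools may account for the XX change, where the Hox median minus the mesonephros median was -0.17. The spread between the XX null libraries was wider, at 0.26, and the mesonephros list did not pass in XX (camera adjusted p = 0.11), so this is not settled. The XX Hox call was also lost without XX wild type replicate 1 (0.09) and without XX Kdm6b-null replicate 1 (0.20). In XY the Hox median minus the mesonephros median was 0.40, with a spread of 0.55 between the null libraries. More mesonephric tissue therefore cannot be told apart there from a change in Hox expression either. Loss of a demethylase that removes a repressive mark would be expected to lower its target genes, opposite to the direction seen for Hox genes. Neither the mark nor its targets were measured here, so a direct or indirect effect of Kdm6b loss on Hox genes was not tested and stays open.

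The Sry regulators were picked out because their effects differed between the sexes, with a median log2 difference of -0.41, or -0.25 without XX wild type replicate 1. The coelomic epithelium genes were picked out for a difference of 0.49, which was 0.16 without XX wild type replicate 1, 0.43 without XY Kdm6b-null replicate 2 (its camera call was lost in both cases), 0.32 without XX Kdm6b-null replicate 1 and 0.81 without XX wild type replicate 2. Endothelial genes differed by -0.57 between the XY and XX effects. Erythroid genes differed by 1.17, which was 0.37 without XY Kdm6b-null replicate 2, 0.65 without XX wild type replicate 2 and 1.91 without XY Kdm6b-null replicate 1. Macrophage genes differed by 0.46, or 0.28 without XX wild type replicate 1 and 0.88 without XX wild type replicate 2. Each of these differences passed by camera with the preset correlation and not with an estimated one.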

How the results depend on the processing

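The correction for GC content and transcript length and the testis pathway without Sry (a median of -0.43 in XY) were chosen after the data were seen, and the other alternatives before. The planned edgeR and DESeq2 fits on recovered reads, and the joint edgeR fit of XY against XX wild type, were not run, since the steps lay too near 1 for the screen of recovered reads. In XY the count of 0 genes became 1 without the variance trend (Kdm6bos), 2 with GC and length trends removed (Kdm6b and Gm15772), and 0 to 2 when libraries were left out in turn. In XX it became 10 with all 8 libraries in 1 fit (5 higher and 5 lower) and 0 to 3550 on leaving out libraries, and for the difference it became 0 to 44. With the replicate number as a block there were 23 calls in XY (7 higher and 16 lower), 2 in XX and 9 lists in XX; the correlations of same-numbered libraries were 0.24 in XY and -0.06 in XX, and 2 pairs do not show that the numbers pair the samples. The lists past the threshold fell from 8 in XY, 5 in XX and 6 for the difference to 0 in each with an estimated correlation. That setting cannot change the median of -0.43 of the testis pathway in XY, whose camera adjusted p was 0.24 there (1.7e-10 to 0.24 over its alternatives). Leaving out libraries gave 5 to 10 lists in XX and 6 to 12 for the difference. Pearson's correlation between the sexes was 0.08 without a filter and 0.06 to 0.23 on leaving out libraries. Spearman's was 0.09 and 0.07 to 0.23. Leaving out single XY libraries changed the sign of the median of the called lists of germ cells (-0.04 to 0.72), erythroid genes (-0.28 to 1.26) and endothelium (-0.35 to 0.03); the cause was not tested, nor was that of the other changes above. Over 21 settings, 319 of 355 list values stayed on their side of the threshold and 9 of the 355 had a median of the other sign; 34 lost the call in the same camera direction, 18 of them with the estimated correlation, and 2 in the other direction. Of 5392 values for 341 single-gene results, 167 passed the threshold under an alternative, 89 of them without XX wild type replicate 2 and 50 without XX wild type replicate 1; 88 had another sign. Under both other scalings the median of all genes lay between -0.02 and 0.012 in XX and between -0.001 and 0.004 in XY. Depth limits genes near 3 counts, which cannot be separated from 0.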

Other observations

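Apoa1, an apolipoprotein of liver and yolk sac, had 1398 and 43.5 normalized counts in the XX wild type libraries and 6.975 and 5.051 in the null, and Ttr, the thyroid hormone carrier transthyretin, had 900.3 and 104.2 against 6.975 and 8.082. The adrenal steroid hydroxylase Cyp21a1, named like them from the authors' calls in XX, had 189.2 and 4.046 normalized counts in wild type and 0.9965 and 1.01 in the null, the null values lying below 3 counts. In XY libraries Apoa1 had 5.935 and 3.988 in wild type and 19.51 and 3.088 in the null (normalized separately).

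H2-D1, a class I antigen of the major histocompatibility region on chromosome 17, was lower in XY null gonads in the authors' deposited table (DESeq2 log2 fold change -1.11, adjusted p = 7.2e-04). It averaged 576.5 ± 2.44 normalized counts in XY wild type and 267.3 ± 70.4 in XY Kdm6b-null gonads (SD, n = 2 each), while in XX it averaged 329.9 ± 126 and 459.1 ± 121 (SD, n = 2 each). Ccnd1, which drives entry into the cell cycle, averaged 2783 ± 1.68 and 1976 ± 210 in XY and 3021 ± 62.1 and 2156 ± 60.6 in XX wild type and null gonads (SD, n = 2 each, normalized separately), and H2-D1 and Ccnd1 were named after their values were seen. In XX the log2 fold changes were related to transcript length (Spearman 0.20 across 16981 genes) and GC content (0.22), with a median of -0.09 in the shortest and 0.09 in the longest of 4 equal bins of genes, and in XY these correlations were 0.03 and 0.08 across 16774 genes. Genes are not independent replicates, so no p is given.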
